A study of Mus musculus with 9 samples.

How the data were processed

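miRNA levels were measured on 9 Agilent mouse miRNA microarrays in MLE12 cells, an immortalised mouse lung epithelial line that makes surfactant. Groups and replicate numbers came from the sample titles: 3 arrays of untreated cells, 3 arrays of cells given 10% cigarette smoke extract (CSE) for 2 h and 3 arrays of cells given 10% CSE for 10 h. Per the labels' protocols, CSE was made by bubbling cigarette smoke through serum-free medium and filtering it, RNA was extracted with a miRNeasy kit, and 100 ng of total RNA per array was labelled with Cy3. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Untreated cells carry no time in the sample labels, and no untreated group matched to 10 h was given. The deposited series table names its untreated columns as 2 h controls, so the 10 h comparison may also hold time in culture.

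Each array's values are spot intensities, and per the file headers they were made with Agilent Feature Extraction, which the submitters' processing notes give as version 10.7.1.1, with background subtraction and no scaling between arrays. The deposited series table holds log2 values per miRNA; it was set against the arrays, and each of its 9 columns correlated best with an array of its own group (r from 0.98 to 0.999 for miRNAs detected on all arrays). Its column medians ran from -3.32 to -2.93, the value at which each column holds its undetected miRNAs, and how the authors scaled it is not given in the sources used here. In 6 of the 9 columns the number in the column's name was not that of the best-matching array, so the columns were used by group only, as an alternative. The columns numbered 2 matched best with untreated replicate 1, 2 h replicate 2 and 10 h replicate 1; a pairing of 2 h arrays by the table's numbers would rest on matching values and was not fitted. For untreated and 10 h arrays these matches give the same pairs as the titles' numbers. That table was floored at the 5th percentile of its detected values, 0.30 on the log2 scale, and 176 of the tested miRNAs were named in it.

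An array held 13000 spots that were not controls, for 1857 probes of 650 miRNAs, 39 of them viral; 715 control spots were left out, as were spots carrying the software's outlier flags (252 to 351 per array). No spot was saturated. Between 22.0% and 29.6% of the spots were well above background, and the number of arrays limits the precision of every value. The median background-subtracted signal of each probe's spots was scaled by the array's 75th percentile over the 290 probes detected on all arrays, because under 50% of the probes were detected. A probe counted as detected where at least 0.5 of its spots were well above background. Scaling factors ran from 0.622 to 1.83. Signals were then floored at the 5th percentile of the scaled signals of spots well above background, 11.9 (3.57 on the log2 scale), and taken to log2, so that a fall to the floor is understated. A group wholly at the floor has no spread by construction, which can make standard errors and p-values of such miRNAs too small. Each miRNA was represented by its brightest probe (1 to 4 probes per miRNA). The 193 miRNAs whose chosen probe was detected on all 3 arrays of at least 1 group were tested, and 157 were detected on all 9. miRNA names are those of the array's design; 138 of the 193 matched a miRNA gene of the mouse RefSeq table (assembly GRCm38.p6) and 55 kept only the array's name. The files name no genome build, so no coordinates are given.

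The 3 comparisons (2 h and 10 h of CSE against untreated cells, and 10 h against 2 h) were fitted together over all arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 changes are standard errors from that fit, intervals are 95% confidence intervals, and all tests were two-sided. Where no array of a group had the miRNA well above background, the change is given as at least N-fold: the brighter group's mean over its replicates against the dimmer group's mean of, per array, the higher of the lowest scaled signal among probes well above background and the probe's own. Changes in 27 lists of miRNAs fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01 for the 16 lists with at least 3 tested members, with Benjamini-Hochberg adjustment over the lists of a comparison. The alternatives were camera with an estimated correlation and fry, which asks whether the list itself moved and allows for correlation between its members. The lists covered the families of let-7, miR-15, miR-17, miR-23, miR-26, miR-29, miR-30, miR-99, miR-130, miR-181, miR-200 and miR-221. They also covered p53-induced, inflammation-linked, hypoxia- and oxidative-stress-linked and smoke-linked miRNAs, the imprinted Dlk1-Dio3 region, the Sfmbt2 intron cluster, G-rich miRNAs that can follow RNA quality, passenger strands, markers of 6 other cell types and miRNAs of mouse gammaherpesvirus. Because both exposures were set against the same untreated arrays, the correlation of their changes was compared with 987 simulations of unchanged groups made by resampling the arrays' deviations from their group means (13 of 1000 draws had no spread). These draws did not keep same-numbered arrays together. As an alternative, 791 of 1000 further draws that kept the untreated and 10 h pairs were used. Draws that repeated no pair were left out, because their group means do not deviate.

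The miRNAs named were chosen by a rule fixed before the data were examined. Per comparison with untreated cells these were, among miRNAs past the threshold whose 3 treated arrays all lay on one side of the 3 untreated arrays, up to 12 largest rises and 12 largest falls; where fewer than 10 qualified, also the 10 with the smallest unadjusted p; up to 3 tested members of each list with the largest changes; the 10 brightest miRNAs of untreated cells; and always miR-21, miR-34a, miR-146a, miR-155, miR-210, miR-200c and let-7c. For 10 h against 2 h the limits were 5 rises and 5 falls.

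The fit was tested on simulated data for the 10 h comparison, with independent noise for each miRNA and array and no floor. With 193 miRNAs, 20 simulated sets and 20 miRNAs changed per size, it recovered 36.5% of log2 changes of 0.5, 86.8% of changes of 1 and 99.8% of changes of 2, with 3.08% of its calls false. These rates do not cover deviations that miRNAs share on an array, or values at the floor. In 200 simulated lists of 23 miRNAs for that comparison with independent noise, camera called 3% of unshifted lists and 100% of lists shifted by -0.4. Alternatives covered the scaling (75th percentile over all probes, quantile, none), normexp background correction with an offset of 50, the floor (0.5 and 2 times), the probes and spots of a miRNA, the software's total signal per miRNA, the filter, the variance model, the slide and the replicate number as blocks, the authors' processed table, and leaving out each array. The files hold no mean spot signal, so normexp used the median spot signal, on spots without outlier flags for the spot or its local background, because a few flagged spots otherwise set the fitted background. With no filter, miRNAs at the floor on every array were left out because they have no spread. Arrays lay on 2 slides; slide 1 held 1 untreated, 1 2 h and 2 10 h arrays, and slide 2 held 2, 2 and 1. The replicate numbers of the titles were checked for pairing by the correlation of same-numbered arrays' deviations from their group means. All 3 pairs of untreated and 10 h arrays correlated (r from 0.358 to 0.621), so for that comparison the numbers were taken to pair the arrays and a fit with the replicate number as a block was made on these 6 arrays alone. Of the pairs with 2 h arrays, 1 of 3 with untreated and 0 of 3 with 10 h arrays had a correlation over 0.1, so there the numbers were not taken to pair them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.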

Results

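The response of MLE12 mouse lung epithelial cells to cigarette smoke extract (CSE), a medium through which cigarette smoke has been bubbled, was measured on miRNA microarrays. The series compared untreated cells with cells exposed to 10% CSE for 2 h and for 10 h, with 3 arrays per group, to find miRNAs whose level the extract alters. Untreated arrays detected 186 to 208 miRNAs, 2 h arrays 167 to 200 and 10 h arrays 187 to 212. The correlation of log2 signals across the 193 tested miRNAs was between 0.966 and 0.994 for arrays of one group and between 0.960 and 0.995 for arrays of different groups.

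The brightest signals in untreated cells came from miR-720 (14.74 ± 0.35 on the log2 scale, SD, n = 3), miR-21 (13.85 ± 0.54) and miR-500 (12.61 ± 1.22). They were followed by let-7a (12.31 ± 0.07), let-7c (12.24 ± 0.15), let-7f (12.20 ± 0.13), miR-125b-5p (12.15 ± 0.45), miR-16 (12.15 ± 0.07), miR-23a (12.01 ± 0.32) and let-7b (11.93 ± 0.31). None of these 10 passed the limma test at either time. Their log2 changes lay between -0.77 and 0.12 at 2 h and between -1.11 and 0.15 at 10 h. Both lowest values belonged to miR-500, whose untreated arrays differed most. No member of the miR-200 family, which maintains the epithelial state, was detected on any array, miR-200c included. miR-146a, an NF-kB-induced miRNA, was detected on 0 arrays as well. Markers of blood, endothelial and striated muscle cells and of hepatocytes were detected on no array. Of 5 markers of fibroblasts and smooth muscle, 1 was detected on some array and 0 were tested. Of 4 neuronal markers only miR-128 was tested, with a log2 change of 0.00 ± 0.16 at 2 h and 0.02 ± 0.16 at 10 h (SE).

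After 2 h of CSE, 3 of 193 miRNAs changed: miR-805 rose, and the passenger strands miR-29b* and let-7a*, the less used strands of their hairpins, fell. The miR-805 signal was 3.12-fold higher, 6.56 ± 0.28 against 4.92 ± 0.21 on the log2 scale (SD, n = 3 each), a change of 1.64 ± 0.18 (SE, adjusted p = 0.00174, limma). miR-29b* fell by 1.38 ± 0.18 on the log2 scale (adjusted p = 0.0034) and was well above background on 2 of the 3 exposed arrays and on all 3 untreated arrays. It lay at the floor in 2 h replicates 1 and 3, so its fall is a lower limit. The spread in the fit also takes in the 10 h arrays, all at the floor for this miRNA, so its p-value may be too small. let-7a* fell by 1.06 ± 0.21 (adjusted p = 0.0379). Each of these 3 miRNAs had all 3 exposed arrays on one side of all 3 untreated arrays. On slides 1 and 2 the differences were 1.72 and 1.60 for miR-805, -1.16 and -1.49 for miR-29b*, and -0.86 and -1.17 for let-7a*. Their shared sign follows from that separation and is no further test.

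The other miRNAs among the 10 with the smallest unadjusted p at 2 h did not pass. miR-30c-2* (-0.87 ± 0.21), miR-15b* (-0.67 ± 0.17), miR-20a* (-0.68 ± 0.18) and miR-99b* (-0.76 ± 0.20) each had an adjusted p of 0.114. miR-21*, the passenger strand of miR-21, was not well above background on any 2 h array and was on all 3 untreated arrays, at least 2.10-fold lower at 2 h (adjusted p = 0.119). miR-712 (-0.84 ± 0.29) and miR-106b* (-0.52 ± 0.18) each had an adjusted p of 0.362. At an unadjusted p under 0.05, 1 miRNA was higher and 13 were lower. The call of let-7a* was lost in 18 of 29 alternatives, among them no scaling (adjusted p = 0.17), normexp background correction (adjusted p = 0.999) and the set detected on all 9 arrays (adjusted p = 0.0584). It was lost with the slide as a block (adjusted p = 0.0666) and without any one of untreated replicates 1 and 3, the 3 replicates of 2 h, and 10 h replicates 1 and 2 (adjusted p from 0.0608 to 0.223). Leaving out 1 array gave log2 changes from -1.14 to -0.98 for let-7a*. With no scaling and with normexp no miRNA passed at 2 h: miR-805 had an adjusted p of 0.17 and 0.412, and miR-29b* of 0.158 and 0.999. With the doubled floor miR-29b* did not pass either (adjusted p = 0.188). Without untreated replicate 2 the number of changed miRNAs was 9.

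After 10 h of CSE, 12 miRNAs changed, 3 upward and 9 downward, and 7 of the 9 that fell were passenger strands. These calls are from the fit without pairing. With untreated and 10 h arrays paired by replicate number, miR-705, miR-20a* and miR-99b* did not pass. miR-805 was 7.69-fold higher than in untreated cells, 7.86 ± 0.13 against 4.92 ± 0.21 (SD, n = 3 each), a log2 change of 2.94 ± 0.18 (SE, adjusted p = 1.27e-05, limma). miR-709, a nuclear miRNA that acts on the processing of the miR-15a/16-1 transcript, rose 2.52-fold, from 11.71 ± 0.33 to 13.04 ± 0.27 (adjusted p = 0.011). miR-705 was not well above background on any untreated array and was on all 3 arrays at 10 h, at least 1.58-fold higher (adjusted p = 0.0245). Among the falls, let-7a* dropped by 1.69 ± 0.21 and was 3.24-fold lower (adjusted p = 0.00125). miR-29b* was not well above background on any array at 10 h and was at least 3.60-fold lower (adjusted p = 0.00125), and miR-20a* likewise was at least 2.45-fold lower (adjusted p = 0.0149). For both, all 3 arrays at 10 h lay at the floor, as did all 3 untreated arrays for miR-705. Those groups have no spread by construction, so these p-values do not measure it there.

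The other falls at 10 h lay between 1.74-fold and 2.54-fold. The passenger strand miR-30c-2* fell by 1.18 ± 0.21 on the log2 scale (adjusted p = 0.011) and was well above background on 1 of 3 arrays at 10 h. All 3 of these arrays lay at the floor, so its fall is a lower limit and its p-value rests on no spread at 10 h. miR-106b* fell by 1.03 ± 0.18 (adjusted p = 0.011), miR-15b* fell by 0.83 ± 0.17 (adjusted p = 0.0203) and miR-99b* fell by 0.80 ± 0.20 (adjusted p = 0.0485). miR-712, which maps to the spacer of the ribosomal RNA precursor gene, fell by 1.34 ± 0.29 (adjusted p = 0.0245). miR-125a-3p, the strand opposite miR-125a-5p, fell by 1.00 ± 0.24 (adjusted p = 0.0473). miR-21* was not well above background on any array at 10 h, at least 3.03-fold lower, and did not pass (adjusted p = 0.0735). All 12 changed miRNAs had their 3 exposed arrays on one side of the 3 untreated arrays, so each slide alone had to give the same sign. On slides 1 and 2 the log2 differences were 3.20 and 2.79 for miR-805, 1.78 and 0.99 for miR-709, and -1.84 and -1.31 for let-7a*. Of the 6 changed miRNAs with several measured probes, 5 had all of them changed in one direction, and 1 of 3 probes of miR-125a-3p lay at the floor in every group. Sizes differed: the second measured probe of miR-712 changed by -0.51, and the other probes of miR-705 by 0.24 to 0.43. let-7a*, miR-106b*, miR-15b*, miR-20a*, miR-30c-2* and miR-99b* each rested on 1 measured probe, so a faulty probe could not be checked for their falls. At an unadjusted p under 0.05, 3 miRNAs were higher and 18 lower.

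**Figure D1:**
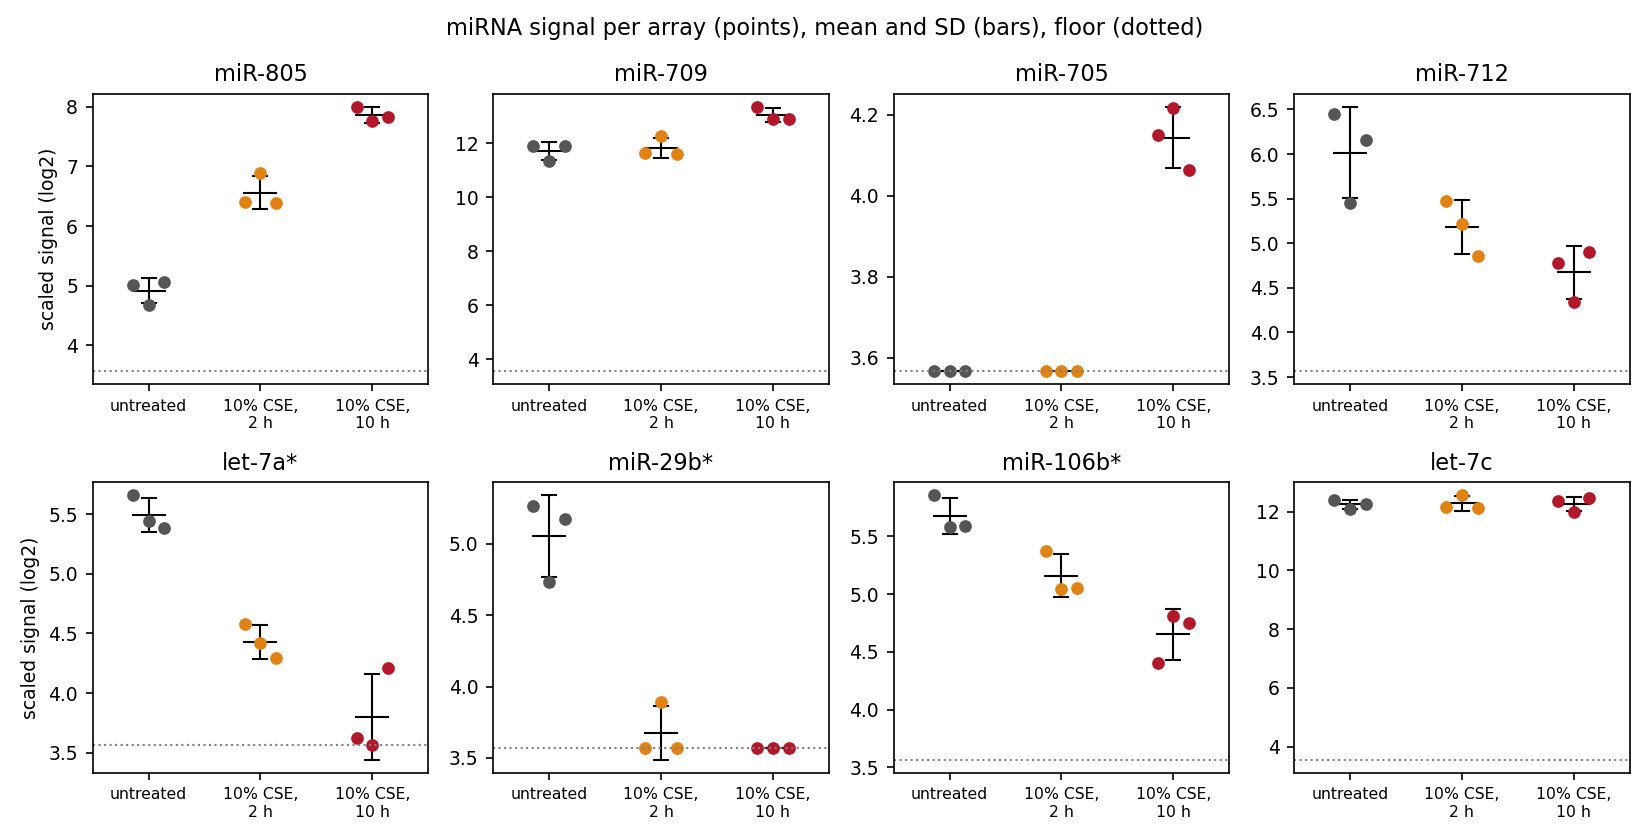
Scaled signal (log2, vertical axes that differ between panels and do not start at 0) of 8 miRNAs in untreated cells and after 2 h and 10 h of 10% CSE; points are single arrays, bars the mean and SD of 3 arrays, and the dotted line the floor at 3.57. miR-805 climbs from a mean of 4.92 to 6.56 and 7.86, the 3 passenger strands drop toward the floor, and let-7c stays near 12.24.

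With the slide as a block, 7 miRNAs passed at 10 h, all of them among the 12. In a fit of the 6 untreated and 10 h arrays with the replicate number as a block 11 passed, not all of them among the 12. There miR-20a* (adjusted p = 0.0583), miR-99b* (adjusted p = 0.0766) and miR-705 (adjusted p = 0.154) did not pass. Because no untreated group was matched to 10 h, time in culture was not separated from exposure. Leaving out untreated replicate 3 left 4 changed miRNAs, leaving out 10 h replicate 1 left 3 and leaving out 10 h replicate 2 left 5. Leaving out together the 3 arrays that stood apart from their groups left 4. In each of these cases of arrays left out, all were among the 12. miR-709 was lost without 10 h replicate 1 (adjusted p = 0.056). Normexp background correction left 2 rises and no falls, and the calls of miR-705, miR-712, miR-125a-3p, miR-15b* and miR-99b* were each lost in at least 13 alternatives.

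The levels at 10 h and 2 h were compared directly, a comparison in which time in culture was not separated from exposure. Only miR-805 passed: it was 2.46-fold higher at 10 h than at 2 h, with 7.86 ± 0.13 against 6.56 ± 0.28 (SD, n = 3 each). The log2 difference was 1.30 ± 0.18 (SE, adjusted p = 0.011, limma), and 1.48 and 1.19 on slides 1 and 2. The difference for miR-709 was 1.21 ± 0.24 (adjusted p = 0.0595) and that for miR-705 0.58 ± 0.12 (adjusted p = 0.0814). At an unadjusted p under 0.05, 3 miRNAs were higher and 4 lower at 10 h. The call of miR-805 was lost without 2 h replicate 1 or 3 or any one of the 10 h replicates (adjusted p from 0.0562 to 0.0912). It was also lost with normexp (adjusted p = 0.0824), with no scaling (adjusted p = 0.378) and with the replicate number as a block (adjusted p = 0.0616). That number was not taken to pair 2 h and 10 h arrays. Leaving out 1 array gave log2 differences from 1.22 to 1.46 for miR-805.

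Most passenger strands had lower values after CSE. Of 115 on the array, 23 were tested, and 19 of them were lower after 2 h and 23 after 10 h. At 10 h, 18 were lower with the 75th percentile over all probes and with quantile normalization and 17 with no scaling, and at 2 h 16, 19 and 22. Their median log2 change was -0.25 at 2 h (camera adjusted p = 1.48e-11) and -0.42 at 10 h (adjusted p = 3.89e-10). With an estimated correlation of 0.235 both calls were lost, with adjusted p = 0.193 at 2 h and adjusted p = 0.265 at 10 h. The median at 10 h was smaller under other choices: -0.26 with the 75th percentile over all probes and with quantile normalization, -0.23 with no scaling, -0.27 with normexp, -0.21 with the mean over all probes and -0.16 with no filter. Over all miRNAs 2 of them fell at 2 h and 7 at 10 h. Adjusted over the list alone 7 fell at 2 h and 10 at 10 h. At 10 h against 2 h the median was -0.11 (camera adjusted p = 0.0186, and adjusted p = 0.772 with an estimated correlation). That call was also lost without 2 h replicate 2 (adjusted p = 0.157), 10 h replicate 1 (adjusted p = 0.254) or 10 h replicate 2 (adjusted p = 0.0598). With fry, which tests whether the list itself moved, the list passed at 10 h (adjusted p = 0.0289) and not at 2 h (adjusted p = 0.13) or between the times (adjusted p = 0.98). With members not well above background at their bound the medians were -0.25 at 2 h and -0.42 at 10 h. Lower bounds of members already below the median, as miR-29b*, miR-20a* and miR-21* were at 10 h, cannot move it. The unchanged medians thus say little about the floor. On slides 1 and 2 the medians were -0.01 and -0.43 at 2 h, and -0.41 and -0.54 at 10 h, and with the slide as a block they were -0.25 and -0.39.

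Guide strands paired with the passengers by name did not share this change. For 22 of the passenger strands the guide strand was tested as well. Strands were assigned and paired by the array's names, in which a star marks the passenger. Dimmer strands without a star count among the other miRNAs. An example is miR-125a-3p, at 5.32 in untreated cells against 8.89 for miR-125a-5p. In untreated cells miR-17* (6.57) and miR-140* (8.01) were brighter than miR-17 (5.75) and miR-140 (7.58). miR-24-2* and miR-30c-2* were paired with miR-24 and miR-30c, whose names give no single hairpin. Other guides, let-7a and miR-29b among them, were not checked for further hairpins, so a pair need not come from a single hairpin. The median log2 change of the guides was -0.06 at 10 h against -0.47 for their passengers. At that time 20 of 22 passengers lay below their guide, and 0 of the 22 guides passed the test in the fit without pairing. let-7a changed by 0.04 ± 0.17 where let-7a* fell, miR-29b by -0.09 ± 0.23 where miR-29b* fell, and miR-21 by -0.10 ± 0.32. The exceptions were miR-674, with -0.58 ± 0.17 (adjusted p = 0.107) against -0.02 for miR-674*, and miR-18a, with -0.11 ± 0.19 against -0.00012 for miR-18a*. The median of the passenger strands at 10 h lay below that of all tested miRNAs by between 0.17 and 0.39 under the 5 ways of scaling or background correction. The median of all tested miRNAs itself moved from -0.05 to 0.09 with the 75th percentile over all probes and to 0.15 with no scaling.

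**Figure D2:**
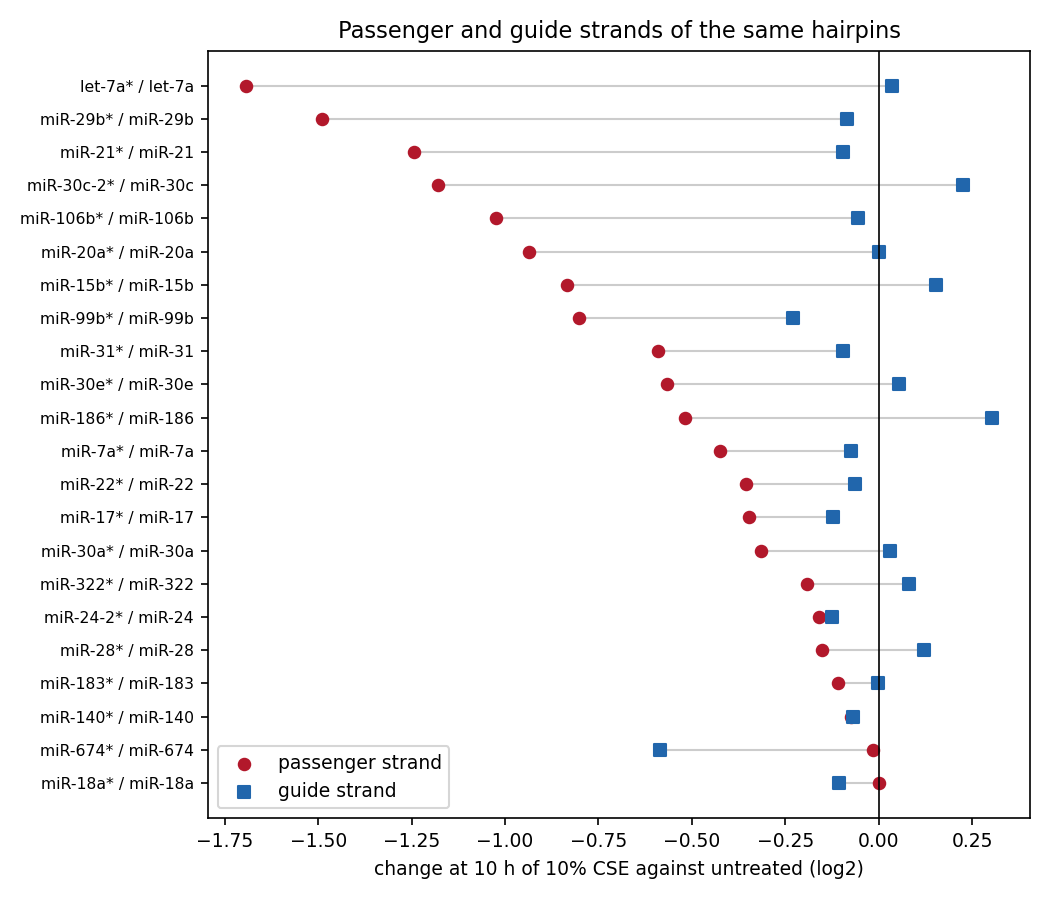
Log2 change at 10 h of 10% CSE against untreated cells (horizontal axis) for 22 pairs of passenger strand (circles) and guide strand (squares) paired by name, each the difference of 2 means of 3 arrays. Passengers lie below their guides in 20 of 22 pairs, from -1.69 for let-7a* to -0.00012 for miR-18a*.

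No other list passed camera in any of the 3 comparisons. The smallest adjusted p among them was 0.873 at 2 h, 0.292 at 10 h and 0.271 for 10 h against 2 h. All 9 members of the let-7 family, which restrains growth genes, were tested and none passed. The median was 0.03 at 2 h and 0.04 at 10 h, with let-7e (0.07 ± 0.18), let-7f (0.05 ± 0.17) and let-7d (0.03 ± 0.17) largest at 2 h and let-7f (0.10 ± 0.17), miR-98 (0.09 ± 0.14) and let-7g (0.08 ± 0.13) at 10 h. let-7c changed by 0.03 ± 0.17 and 0.02 ± 0.17. In the growth-promoting miR-17 family 10 members had medians of -0.06 at both times. miR-17 was at -0.21 ± 0.14 at 2 h and -0.12 ± 0.14 at 10 h, miR-18a at -0.13 ± 0.19 and -0.11 ± 0.19, miR-19a at -0.10 ± 0.20 at 2 h and miR-19b at -0.12 ± 0.12 at 10 h. Of the cell-cycle-targeting miR-15 family 6 members had medians of 0.03 and 0.12. They were led by miR-497 (0.45 ± 0.29 and 0.36 ± 0.29), with miR-15b at 0.04 ± 0.14 and 0.15 ± 0.14 and miR-195 at 0.04 ± 0.18 and 0.13 ± 0.18. All 6 were higher at 10 h; camera gave an adjusted p of 0.292, and 0.0459 with the replicate number as a block on the untreated and 10 h arrays. Without the block it was 0.985 with an estimated correlation of 0.478, and fry gave 0.924.

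Stress-linked lists held no changed member. The 6 tested p53-induced miRNAs had medians of -0.0034 and -0.04. miR-34a changed by 0.00 ± 0.10 at 2 h and -0.04 ± 0.10 at 10 h. miR-34b-5p changed by -0.11 ± 0.39 and -0.07 ± 0.39, miR-34c by -0.06 ± 0.42 and -0.09 ± 0.42, miR-107 by 0.06 ± 0.09 at 2 h and miR-194 by 0.11 ± 0.14 at 10 h. Of 4 inflammation-linked miRNAs, with medians of 0.06 and -0.08, none passed. miR-21 changed by -0.08 ± 0.32 and -0.10 ± 0.32 and miR-146b by 0.09 ± 0.29 and 0.13 ± 0.29. miR-212 changed by 0.09 ± 0.15 and -0.15 ± 0.15, and miR-155 by 0.04 ± 0.16 and -0.07 ± 0.16. The 5 hypoxia- and oxidative-stress-linked miRNAs had medians of 0.03 and -0.13. miR-210, the hypoxia-induced miRNA, was 0.48 ± 0.72 and -0.13 ± 0.72, miR-503 was -0.32 ± 0.50 and -0.37 ± 0.50, and miR-27a was -0.14 ± 0.12 and -0.13 ± 0.12. The 19 tested miRNAs of a list recalled as lower in the lungs of smoke-exposed rats had medians of -0.01 and -0.04. The largest changes included miR-219 (-0.11 ± 0.24) and miR-30e (-0.08 ± 0.08) at 2 h, and miR-99b (-0.23 ± 0.16), miR-30c (0.23 ± 0.12) and miR-26a (-0.19 ± 0.10) at 10 h.

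The remaining families held no changed member either. The medians at 2 h and 10 h were -0.01 and 0.05 for the 5 members of the miR-30 family, with miR-30b at -0.05 ± 0.10 and 0.08 ± 0.10. They were -0.09 at both times for the 3 of miR-29, with miR-29c at -0.10 ± 0.17 at both times and miR-29a at -0.05 ± 0.20 and -0.02 ± 0.20. For the 5 of miR-23 they were -0.08 and -0.11, with miR-27b at -0.12 ± 0.14 and miR-24 at -0.08 ± 0.20 at 2 h. At 10 h miR-23b was at 0.15 ± 0.17 and miR-23a at 0.15 ± 0.22. The miR-26 family had medians of -0.03 and -0.04, with miR-26b at -0.01 ± 0.14 and 0.11 ± 0.14. The miR-221 family had 0.01 and 0.02, with miR-221 at 0.01 ± 0.18 and -0.09 ± 0.18 and miR-222 at 0.01 ± 0.37 and 0.14 ± 0.37. The 3 tested members of miR-181 had 0.0049 and -0.02, against means of -0.01 and 0.08. At 2 h miR-181d was at -0.16 ± 0.22, miR-181a at 0.11 ± 0.35 and miR-181b at 0.00 ± 0.16, and at 10 h miR-181a was at 0.29 ± 0.35. The 5 of miR-99 had 0.02 and -0.10, with miR-100 at -0.07 ± 0.15 and -0.10 ± 0.15 and miR-125a-5p at 0.05 ± 0.18 and -0.19 ± 0.18. The 5 tested members of miR-130 had -0.02 and 0.03, with miR-301a at 0.05 ± 0.12 and 0.10 ± 0.12. At 2 h miR-130a was at 0.04 ± 0.13 and miR-148a at -0.04 ± 0.15, and at 10 h miR-152 was at -0.05 ± 0.20 and miR-148b at 0.04 ± 0.18.

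Of 32 miRNAs of the imprinted Dlk1-Dio3 region on the array 2 were tested. miR-410 was -0.75 ± 0.33 and -0.83 ± 0.33 (adjusted p = 0.647 and 0.335) and miR-494 was 0.15 ± 0.31 and -0.19 ± 0.31. The 6 tested members of the Sfmbt2 cluster had medians of -0.05 and 0.09. The largest changes were miR-467f (-0.43 ± 0.50), miR-466g (0.19 ± 0.51) and miR-669f (-0.18 ± 0.31) at 2 h and miR-669a (0.15 ± 0.25), miR-669f (0.11 ± 0.31) and miR-466f-3p (0.11 ± 0.53) at 10 h.

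The 14 tested G-rich miRNAs, which can follow RNA quality, had medians of 0.03 at 2 h and -0.06 at 10 h, and 2 of them, miR-709 and miR-705, rose at 10 h, both also when adjusted over the list alone. miR-714 was -0.42 ± 0.49 and -1.05 ± 0.49 (adjusted p = 0.494 at 10 h), and at 2 h miR-1187 was -0.39 ± 0.30 and miR-1895 -0.26 ± 0.20. The mean of the list was -0.02 at 2 h, opposite in sign to its median. Camera pointed up for some lists whose median lay below 0, such as the G-rich list at 10 h and the smoke-linked list at both times.

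The 2 exposures were compared for a shared response. Across the 193 miRNAs the changes at 2 h and 10 h correlated with Pearson's r = 0.854 and Spearman's rho = 0.599; miRNAs are not independent replicates. Unchanged groups simulated against the same untreated arrays gave a mean r of 0.430. The central 95% of simulated values reached up to 0.956, and the observed r lay within this range. Simulated groups could hold several or none of the arrays that stood apart from their groups, while each real group held 1. The range thus may not be that of the real groups, and it does not decide whether the response was shared. The covariance was 0.0993 against a simulated mean of 0.0373, with 95% of simulated values between -0.0307 and 0.178. Resampling same-numbered untreated and 10 h arrays together, chosen after the data were seen, gave a mean r of 0.484 with an upper limit of 0.905, and a covariance between -0.0015 and 0.130. This resampling left out draws that repeated no pair, which is how the real arrays stand, so it has the same limit. miR-805 rose and miR-29b* and let-7a* fell at both times; lists of these lengths drawn independently would share 0.0155 rises and 0.0933 falls. The 3 untreated arrays could not be split, so part of the excess may come from the shared controls.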

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

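The tests of probes, of G-rich miRNAs, of scaling, of background correction, of guide strands, of slide and brightness and of other splits were chosen after the results were seen; the random lists were chosen before their outcome was known.

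The change of miR-805 at 10 h exceeded that at 2 h by 1.30 on the log2 scale, in the direct comparison of the exposed groups. It was the only miRNA whose levels at the 2 times differed past the threshold (adjusted p = 0.011, limma, between 0.000944 and 0.378 over its alternatives). Time in culture was not separated from exposure in this comparison.

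If a single faulty probe per miRNA were behind the rise of miR-805 and miR-709, another measured probe would stay level, but the smallest change at 10 h among the other measured probes was 1.79. For miR-805 these were 2 probes at the floor in untreated cells, and 1 more probe, detected on 0 arrays, was left out. For miR-709, a general rise of G-rich miRNAs, as a drop in RNA quality might give, would lift the other 13 tested members of that list by about as much, and their median at 10 h was -0.15 (SD 0.38, from -1.05 to 0.58 for miR-705) against 1.33. miR-805 is not on that list and matched no miRNA gene of the RefSeq table, and neither RNA quality nor binding of other RNA fragments was tested for it. A response to CSE stays open as a hypothesis.

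If the passenger strands had fallen because all dim miRNAs fell, lists of like brightness would have medians as low at 10 h, and 0% of 10000 random lists did. Their members were drawn independently, so the spread of their medians does not allow for correlation between passenger strands. The guide strands paired with the passengers had a median of -0.0590 (SD 0.18) against -0.47. For scaling, the passengers' mean change minus that of the other miRNAs was -0.52 ± 0.06 (SE between arrays), and the highest upper limit of its 95% interval under 4 scalings was -0.22. A factor common to an array cancels in this difference, apart from the floor, so it cannot show whether such a factor lowered the passengers. Quantile normalization, which does not use a factor per array, gave -0.41 ± 0.08. Background correction stays open, because with normexp all 23 were lower (camera adjusted p = 4.02e-05) but the difference was -0.23 ± 0.12, its interval reached 0.0644 and no passenger strand passed alone. The offset of 50 compresses changes of dim signals by construction. With an estimated correlation between members the list's call ended (adjusted p = 0.265 at 10 h), and no biological explanation of the fall is offered.

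In the deviations from the group means, 1 array of each group, untreated replicate 1, 2 h replicate 2 and 10 h replicate 1, stood apart from the other 6, along a component that took 59.6% of the residual spread. The slide accounted for 5.72% of the spread of the arrays' scores and array brightness for 8.02%, which argues against both. The labels name no shared culture or day. The columns numbered 2 in the authors' table matched these 3 arrays best, and the scores fell into separate ranges by the table's number: 3.52 to 5.37 for number 2, -1.64 to -0.59 for number 1 and -3.73 to -2.56 for number 3. A shared replicate set is thus a possible source that stays open, and no fit paired 2 h arrays by the table's numbers, which reach the arrays only through their values, while for untreated and 10 h arrays the best matches give the same pairs as the titles; no biological explanation was tested.

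In each comparison the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 3 changed miRNAs at 2 h, 12 at 10 h and 1 for 10 h against 2 h, and the highest of the other splits gave 0 in each. At 10 h, 4 of the splits part all 3 same-numbered pairs, as the real one does, and 6 part 1 pair.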

How the results depend on the processing

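Leaving out together the 3 arrays that stood apart and array brightness as a covariate, the replicate block on the untreated and 10 h arrays alone, and the list test under no scaling and normexp were chosen after the data were seen; the other alternatives were fixed before. The count at 10 h (12) was within 1.5 times in 18 of 31 alternatives, that at 2 h (3) in 23 of 30 and that for 10 h against 2 h (1) in 12 of 30. At 2 h, 10 h and 10 h against 2 h the counts were 0, 3 and 0 with no scaling, 9, 19 and 3 with array weights, and 1, 5 and 2 for miRNAs detected on all 9 arrays, where fewer miRNAs were tested. At 2 h and 10 h they were 0 and 2 with normexp and 0 and 1 with the authors' processed table. That table does not name miR-805, let-7a* or miR-29b*. Of the other miRNAs called at 10 h, miR-106b* and miR-712 among them, only miR-709 passed with it. The count at 2 h was 7 with the total gene signal. At 10 h it was 5 with the doubled floor, which hides dim miRNAs, 7 with the mean over all probes, 6 in fits of only the 2 groups compared, 7 with the slide as a block and 4 without the 3 arrays that stood apart. For 10 h against 2 h it was 2 with the 75th percentile over all probes, quantile normalization, the total gene signal, no filter, detection by gene flag, no intensity trend and 2-group fits, and 3 with the mean over all probes. Leaving out 1 array gave 2 to 9 at 2 h, 3 to 15 at 10 h and 0 to 2 for 10 h against 2 h. Calls at 10 h split into 3 rises and 9 falls, 1 and 2 with no scaling, 2 and 0 with normexp, and 3 and 6 with quantile normalization; at 2 h they split into 1 and 2, and into 1 and 1 with quantile normalization and with the 75th percentile over all probes. Except where named as changed by construction, the cause was not tested.

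miR-805 at 10 h passed in all 30 alternatives that held it (log2 change from 1.63 to 3.23), and let-7a* and miR-709 at 10 h in 29 of 30 and 29 of 31; miR-709 was lost with no scaling and without 10 h replicate 1. No called miRNA changed sign except miR-705, at -0.13 with normexp. Of 124 values of named miRNAs not past the threshold, 9 passed in some alternative, miR-21* at 10 h most often, in 7. The passenger median stayed below 0 at both times in all alternatives, from -0.52 to -0.23 at 10 h and from -0.35 to -0.07 at 2 h where the list was tested, and was -0.16 and -0.10 with no filter. For 10 h against 2 h it was 0.00823 with no scaling (adjusted p = 0.000518), where the median of all tested miRNAs was 0.22. Its call was lost with an estimated correlation (medians -0.25 at 2 h, -0.42 at 10 h and -0.11 for 10 h against 2 h), with fry at 2 h (-0.25) and for 10 h against 2 h (-0.11), and, for 10 h against 2 h, with quantile normalization (-0.0713) and without the 3 arrays that stood apart (-0.15). Leaving out 1 array gave -0.15 to -0.0909 for 10 h against 2 h. Of 45 values of other lists, 8 passed in some alternative, among them those of the let-7, miR-15 and miR-30 families at 10 h with normexp. The correlation of the changes at 2 h and 10 h ran from 0.70 to 0.889.

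Of the 9 pairs of same-numbered arrays 4 had a correlation over 0.1 (from -0.70 to 0.62), and 3 of 9 arrays correlated best with their own number. All 3 pairs of untreated and 10 h arrays were among the 4. With the replicate block on these 6 arrays alone 11 miRNAs passed at 10 h, against 6 without a block, and the passenger median was -0.42 (adjusted p = 8.13e-09); calls other than those of miR-20a*, miR-99b* and miR-705 were kept. With the replicate number as a replicate block over all 9 arrays 2 miRNAs passed at 2 h, 9 at 10 h and 0 for 10 h against 2 h. That block includes the 2 h arrays, which the numbers were not taken to pair. Signal over background limits the dim passenger strands: 4 of the 23 were not well above background on any array at 10 h, and their falls are bounds. The fall of miR-30c-2*, at the floor on every array at 10 h, is a lower limit too.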

Other observations

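The arrays that stood apart differed from their groups in named miRNAs. Relative to the mean of the other arrays of its group, miR-210, the hypoxia-induced miRNA, was higher by 2.13 in untreated replicate 1, by 0.84 in 2 h replicate 2 and by 2.03 in 10 h replicate 1 on the log2 scale. miR-31 was higher by 1.2, 1.22 and 1.09 and miR-34c by 1.04, 0.82 and 1.19. In the same arrays miR-503 lay at -1.19, -1.54 and -0.97 and miR-322 at -0.96, -0.75 and -0.71 relative to the others, as did miR-542-3p (-0.68, -1.05 and -0.75), miR-450b-5p (-1.07, -0.87 and -0.84) and miR-351 (-0.65, -1.09 and -0.50). The 7 genes of miR-322, miR-503, miR-351, miR-542 and miR-450 are neighbours on the X chromosome in the RefSeq table, with no other miRNA gene and 1 other gene between them. The standard deviation of miR-210 was 1.23 in untreated cells, 0.71 at 2 h and 1.18 at 10 h. At 2 h replicate 1 (7.33) lay near replicate 2 (7.65) and replicate 3 was low (6.28).

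Of the viral miRNAs on the array 3 were tested. The probe of mcmv-miR-M23-1-5p, a miRNA of mouse cytomegalovirus, was detected on 9 arrays, with 7.06 ± 0.23 in untreated cells, 7.02 ± 0.25 at 2 h and 6.53 ± 0.20 at 10 h (SD, n = 3 each; log2 change at 10 h -0.52, adjusted p = 0.232, limma). That of mcmv-miR-m88-1 was detected on 9 arrays too, at 5.09 ± 0.38, 5.16 ± 0.02 and 5.06 ± 0.13. The probe of mghv-miR-M1-2, of mouse gammaherpesvirus, was detected on 8 arrays, at 4.07 ± 0.44, 4.10 ± 0.68 and 3.83 ± 0.25.

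Of the 193 tested miRNAs, 11.4% had exposed and untreated arrays that did not overlap at 10 h and 6.22% at 2 h; chance gives 10% for 3 arrays against 3.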
